A study of Rattus norvegicus with 8 samples.

How the data were processed

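The samples were primary ventricular cardiomyocytes of newborn rats, plated in 6 cm dishes and transfected with 0.4 µM of a miR-222 precursor (4 arrays) or of a control precursor of scrambled sequence (4 arrays), with RNA extracted by Trizol after 48 h and labelled with biotin by in vitro transcription, per the labels. The intensity values of the deposited table were on a linear scale, from 0.8 to 16339, and had been processed and normalized between arrays by the authors by a method that is not given in the sources used here. No scanner files and no detection calls were used here. The series text names a different Affymetrix rat array, but the identifiers of the table pair with the annotation of the Affymetrix Rat Gene 1.0 ST array, and that annotation was used for gene names. Replicates are numbered in the order in which the samples are listed, and the labels give no replicate numbers, pairing or batches.

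Each value was taken as log2 without a pseudocount, since the table held no zeros. It held 212 values at 1 or below, in 78 probe sets, and 4 of these probe sets were among those called. All probe sets entered the tests, including control probe sets, which could not be recognised by name although leaving them out had been planned. Of the probe sets, 15310 paired with 1 gene, 323 with several genes and 13537 with no gene name. Genes were represented by the probe set with the highest mean among those paired with that gene alone, which gave 14506 genes, and 14481 of the probe sets' gene identifiers were found in a table of current symbols, which changed 0 symbols. In 527 genes with at least 2 probe sets the log2 fold changes of the 2 brightest correlated across genes at r = 0.809 (highest of 100 shuffled pairings 0.119), and in 89 of them both were called, 0 in opposite directions.

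Probe sets were compared between miR-222 and control with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 2-sided p-values adjusted over all probe sets by the method of Benjamini and Hochberg and a threshold of 0.05. Gene counts are counts of representative probe sets past that threshold. The median SE over genes was 0.07 log2 units, and the median SD within groups was 0.10 for control and 0.11 for miR-222. Correlations between arrays were 0.989 to 0.993 within groups and 0.983 to 0.989 between groups. Gene lists were tested over the 14506 genes with camera, with the preset correlation between genes of 0.01 and with a correlation estimated from the data, with fry, and with an exact permutation test of the mean centred log2 level of the list over the 8 arrays. The camera p-values were adjusted over the 29 lists. Counts given as adjusted over the list alone use p-values adjusted over the measured members of that list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

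The 29 lists were written before the data were examined, as were the comparison, the named-gene rule and most alternatives. They hold the targets named by the study, published targets of miR-221 and miR-222, G1/S and DNA replication, G2/M and mitosis, inhibitors of cyclin-dependent kinases, fetal and hypertrophic genes, sarcomere and cardiomyocyte identity, calcium handling and excitation, fatty acid oxidation, oxidative phosphorylation and glycolysis. Further lists hold markers of fibroblasts and matrix, smooth muscle and myofibroblasts, endothelium, macrophages and leukocytes, and erythroid, Schwann and epicardial cells. The remaining lists hold the interferon response, NF-kappaB and cytokines, apoptosis, p53 targets, FoxO and Akt, the unfolded protein response, heat shock, NRF2, cholesterol synthesis, immediate early genes, TGF-beta and BMP, ribosomal proteins and small RNA machinery. Of 562 genes in the lists 497 were measured. The genes named in the report were the targets named by the study, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, without unnamed symbols, and up to 4 members of each list with the smallest p. Other members, given to complete a count of 5 or fewer or singled out, were chosen after their values were seen, and so was the wording that compares miR-222 replicate 3 with the other arrays.

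The fit was tested on simulated data with the spread of these arrays, with 200 changed probe sets in each of 20 simulations. It recovered 16.5% of changes of 0.25, 54.5% of changes of 0.5 and 88.0% of changes of 1 on the log2 scale, and 5.12% of the calls were false. In the real arrays 5508 probe sets were called, far more than the 200 changed here. The adjusted p depends on that share, so these recovery rates need not hold for the real comparison. Camera with the preset correlation recovered the G1/S list in 100% of 20 simulations in which that list alone was shifted down by 0.3. Genes were drawn independently there, whereas the correlation estimated for that list in the real arrays was 0.439. The recovery therefore does not show how camera performs on correlated genes. Alternatives were a further normalization, filters on dim probe sets, other priors and weights, other rules for several probe sets of a gene, other thresholds, a pseudocount of 32, leaving out each array in turn and leaving out miR-222 replicates 2 and 3 together. A planned test of miR-222 seed sites in 3 prime untranslated regions was not run, since no genome sequence was used here.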

Results

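Gene expression was measured in primary ventricular cardiomyocytes of newborn rats, heart muscle cells kept in short-term culture that are widely used to study cardiac growth. The cells had been transfected for 48 h with 0.4 µM of a miR-222 precursor or with the same dose of a scrambled control precursor. A microRNA precursor is a synthetic RNA from which the cell makes the mature microRNA, and miR-222 shares its seed with miR-221. Each group held 4 arrays. The deposited table gave intensities with a median of 202 to 219 per array, and 15310 of its probe sets paired with a single gene, which gave 14506 genes. The small number of arrays limits the precision, and nothing in the labels says that the arrays came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The scrambled precursor has a sequence of its own, so the comparison holds the effects of both RNAs. Fold changes below are log2 differences of miR-222 minus control with the standard error (SE) of the limma fit, n = 4 in each group.

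The comparison asks which transcripts differed in cardiomyocytes given extra miR-222. Cells with the miR-222 precursor had a 2.34-fold lower level of Hipk2, a kinase that the study is known to have named as a target of the microRNA, at a log2 fold change of -1.22 (SE 0.07). Of 28 measured genes of the entry into S phase and of DNA replication 19 were lower, with a list median of -0.46 (camera adjusted p = 3.64e-08, but adjusted p = 0.460 with an estimated correlation), whereas 3 of 28 genes of mitosis were higher and 25 did not pass, a result that turned on miR-222 replicate 3 (5 higher without it). Kcnip2, an auxiliary subunit of potassium channels, was among the largest rises at 1.67 (SE 0.09). Among matrix and fibroblast genes 15 of 23 members fell (9 without control replicate 3), and among targets and ligands of TGF-beta and BMP signalling 10 of 15, and neither list passed camera with an estimated correlation (adjusted p = 0.460 and 0.400).

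At an adjusted p under 0.05 in limma, 3580 of 14506 genes (24.7%) changed, of which 1692 were higher and 1888 were lower with miR-222. Counts of list members below are to be read beside this share. Among them 525 changed by at least 1.5-fold, 221 higher and 304 lower, and 90 by at least 2-fold, 43 higher and 47 lower. The median size of the changes was 0.32 on the log2 scale, and the range was -1.71 to 1.91. Over all probe sets, including those with no gene name, 5508 (18.9%) passed, 2604 higher and 2904 lower. The 4 miR-222 values lay all above or all below the 4 control values in 4832 genes, which is 33.3% where chance gives 2.86%, and in 3541 of the 3580 changed genes. Principal components were taken over the upper 60% of probe sets by mean level only. The first of them held 62.1% of the variance of these probe sets and separated the groups. Control arrays lay at -0.37 to -0.32 and miR-222 arrays at 0.27 to 0.51. The highest of these values belonged to miR-222 replicate 3, whereas the other 3 lay at 0.27 to 0.30.

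All 3 targets for which the study is known and that paired with a probe set here were lower with miR-222. Hipk2, a kinase that acts on p53 and other transcription regulators, was measured by probe set 10861997 and went from 11.93 ± 0.08 to 10.71 ± 0.12 log2 units (mean ± SD, n = 4 each, limma adjusted p = 5.14e-05). Its relative Hipk1, probe set 10825582, changed by -0.74 (SE 0.05, adjusted p = 8.18e-05), and Cdkn1b, which encodes the cell cycle inhibitor p27 and has probe set 10859254, by -0.39 (SE 0.04, adjusted p = 2.69e-04). Hmbox1, the remaining target, was not paired with a probe set here and was not analysed. The list lay below the other genes by camera (adjusted p = 3.77e-04), and adjusted p = 0.187 with an estimated correlation. All 3 also passed when adjusted over the list alone. These targets belong to the study of these arrays, so the list is no independent evidence of its direction.

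Targets of miR-221 and miR-222 reported in other cells went both ways. Of 23 measured members, 8 fell, 3 rose and 12 did not pass the test, and 8 lower and 6 higher passed when adjusted over the list alone. The receptor tyrosine kinase gene Kit fell by 0.97 on the log2 scale (SE 0.06, adjusted p = 7.89e-05), the metalloproteinase inhibitor gene Timp3 by 0.73 (SE 0.04, adjusted p = 4.95e-05) and the transcription factor gene Ets1 by 0.33 (SE 0.04, adjusted p = 0.00114). The 3 members that rose were Stat5a at 0.27, the retinoblastoma gene Rb1 at 0.26 and Cdkn1c, which encodes the cell cycle inhibitor p57, at 0.36. The list did not stand apart from other genes (camera adjusted p = 0.339), whereas fry, which tests a list by itself, placed it lower (adjusted p = 1.40e-04). Its median of 0.02 differed in sign from its mean of -0.08 and from the direction of both tests. The call of Rb1 was lost without any single array but control replicate 4 or miR-222 replicate 2 (adjusted p up to 0.0904), and that of Cdkn1c without any but control replicate 2 (adjusted p up to 0.104).

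**Figure D1:**
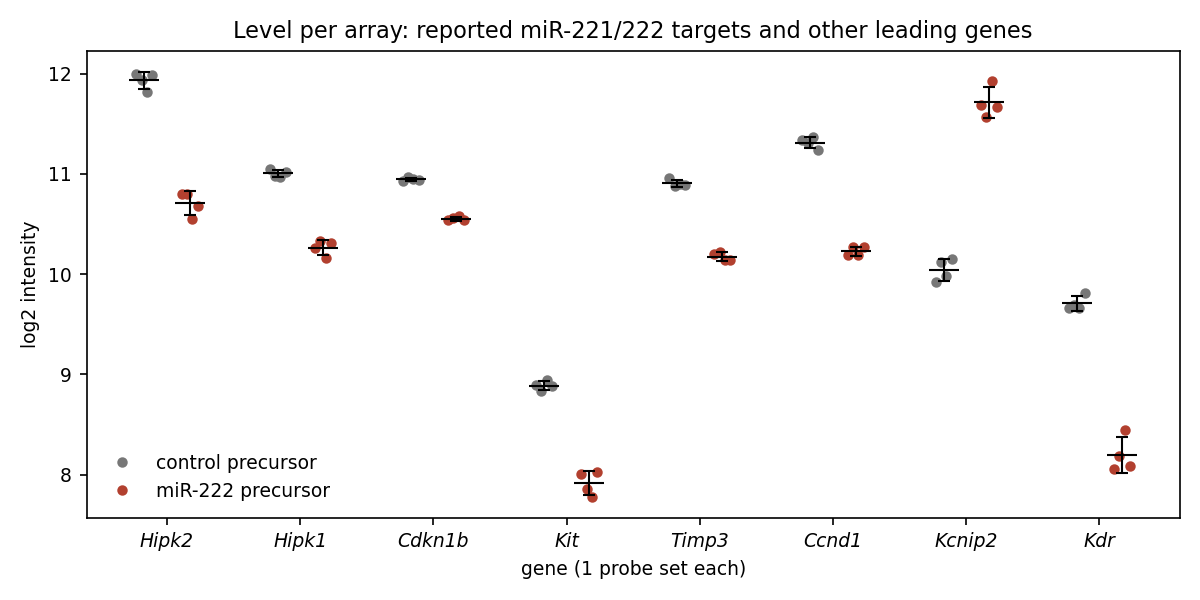
Level of 8 genes on each array, as log2 intensity (vertical axis) by gene (horizontal axis), for 4 control arrays (grey) and 4 miR-222 arrays (red); the horizontal line is the mean and the bar is 1 SD. The groups did not overlap in any of these genes: Kcnip2 was higher with miR-222 (1.67), and the other genes were lower, from -0.39 for Cdkn1b to -1.51 for Kdr.

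The 12 genes with the largest rises spanned signalling, excitation and membrane traffic. Plcxd3, a phospholipase C domain gene, rose most, by 1.91 (SE 0.07, adjusted p = 1.58e-05), which is 3.76-fold. Its level in control cells was dim, at 5.88 log2 units against array medians of 7.66 to 7.77, where background can compress a fold change. Rasgrp1, an activator of Ras, rose by 1.83 (SE 0.10, adjusted p = 4.78e-05), Kcnip2 by 1.67 (SE 0.09, adjusted p = 4.25e-05) and the phospholipase gene Plcd4 by 1.62 (SE 0.08, adjusted p = 3.21e-05). They were followed by the glycosyltransferase gene B3gnt7 at 1.53, the vesicle GTPase gene Rab3b at 1.52, Irag1, a substrate of cGMP-dependent kinase, at 1.46 and Med30 of the Mediator complex at 1.38. Plppr4 at 1.37, the death-associated kinase gene Dapk1 at 1.37 and the chemokine gene Cxcl11 at 1.34 completed the set together with the secretin receptor gene Sctr. Sctr rose by 1.56 with a larger error (SE 0.45, adjusted p = 0.0459), since miR-222 replicate 3 stood at 9.95 log2 units and the other 3 arrays at 7.71 to 8.26. Its call was lost when any single control array or miR-222 replicate 1 was left out, with adjusted p of 0.0826 to 0.103.

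The 12 genes with the largest falls held receptors, basement membrane collagens and an ion channel subunit. C3ar1, the receptor of complement fragment C3a, fell by 1.71 (SE 0.27, adjusted p = 0.00367), and Kdr, the receptor VEGFR2, by 1.51 (SE 0.09, adjusted p = 5.27e-05). Col4a3 fell by 1.51 (SE 0.06, adjusted p = 2.01e-05) and its neighbour on the chromosome, Col4a4, by 1.35 (SE 0.08, adjusted p = 4.95e-05). Both encode chains of basement membrane collagen. The others were the syntaxin gene Stx11 at -1.44, Gpr155 at -1.42, the myosin binding protein gene Mybpc2 at -1.36, the sodium channel subunit gene Scn3b at -1.34, Tnfrsf11b, which encodes osteoprotegerin, at -1.33, the mitochondrial ribosome gene Mrpl36 at -1.31, Gprc5a at -1.30 and the prostaglandin synthase gene Ptgs2 at -1.27. In 10 of them miR-222 replicate 3 was the lowest of the 4 miR-222 arrays, all but Kdr and Mrpl36, and in 3 it lay beyond the 95% limit of Dixon's test for a single array, at 7.23 log2 units against 8.39 to 8.56 for C3ar1, 8.75 against 9.44 to 9.56 for Stx11 and 8.81 against 10.25 to 10.37 for Scn3b. The call of Scn3b was lost when any single control array was left out, with adjusted p of 0.0542 to 0.0606.

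Genes of the G1/S transition and of DNA replication fell, whereas genes of G2 and mitosis did not fall with them. Of 28 measured G1/S and replication genes, 19 were lower, 1 was higher and 8 did not pass, and 21 lower and 1 higher passed when adjusted over the list alone. Ccnd1, encoding cyclin D1, fell by 1.08 (SE 0.05, adjusted p = 1.83e-05), its partner kinase gene Cdk6 by 0.92 (SE 0.07, adjusted p = 1.48e-04), the cyclin E gene Ccne2 by 1.18 (SE 0.16, adjusted p = 0.00159) and Mcm2, part of the replicative helicase, by 0.70 (SE 0.08, adjusted p = 7.07e-04). A further helicase gene, Mcm5, fell by 1.15 (SE 0.16), and the thymidine kinase gene Tk1 was the member that rose, by 0.50. The list lay below the other genes (camera adjusted p = 3.64e-08), but adjusted p = 0.460 with an estimated correlation. Fibroblast markers, whose median was -0.24, fell in the same arrays.

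Of 28 measured genes of G2 and mitosis, 3 were higher and 25 did not pass, with the same counts when adjusted over the list alone. They were Pttg1, the securin that guards chromosome separation, at 0.69 (SE 0.12, adjusted p = 0.00527), the cytokinesis gene Ect2 at 0.49 (SE 0.10, adjusted p = 0.0134) and the cyclin gene Ccnb2 at 0.53 (SE 0.12, adjusted p = 0.0184). Kif20a measured 0.39 (SE 0.15) and did not pass (adjusted p = 0.108). The list did not stand apart from other genes, with a median of 0.06 (camera adjusted p = 0.339, and adjusted p = 0.901 with an estimated correlation). The outcome depended on miR-222 replicate 3, whose list mean was -0.37 on the centred log2 scale against 0.18 to 0.21 in the other 3 miR-222 arrays. Without that array 5 members were higher, the median was 0.22 and the list stood above other genes (camera adjusted p = 0.000931), but adjusted p = 0.641 with an estimated correlation. The call of Ccnb2 was lost without miR-222 replicate 1 (adjusted p = 0.0519) or 4 (adjusted p = 0.0502).

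The list of inhibitors of cyclin-dependent kinases also held Rb1 and Meis1, which are not such inhibitors. Its members went both ways, with 4 of 10 measured members higher, 3 lower and 3 not past the threshold. The counts were the same when adjusted over the list alone. Cdkn1a, which encodes p21, rose by 0.47 (SE 0.04, adjusted p = 3.17e-04) and the phosphatase gene Cdkn3 by 0.68 (SE 0.10, adjusted p = 0.00265), beside Rb1 and Cdkn1c. Cdkn1b, Cdkn2b at -0.27 and the homeobox gene Meis1 at -0.37 (SE 0.05, adjusted p = 0.00215) were lower, the last a factor that holds back cardiomyocyte division. The list did not stand apart from other genes (camera adjusted p = 0.694). The count of 4 higher members was 2 without control replicate 1 or 3 or miR-222 replicate 1, 3 or 4, and Cdkn2b was lost without control replicate 1 or 4 or miR-222 replicate 4 (adjusted p up to 0.056).

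**Figure D2:**
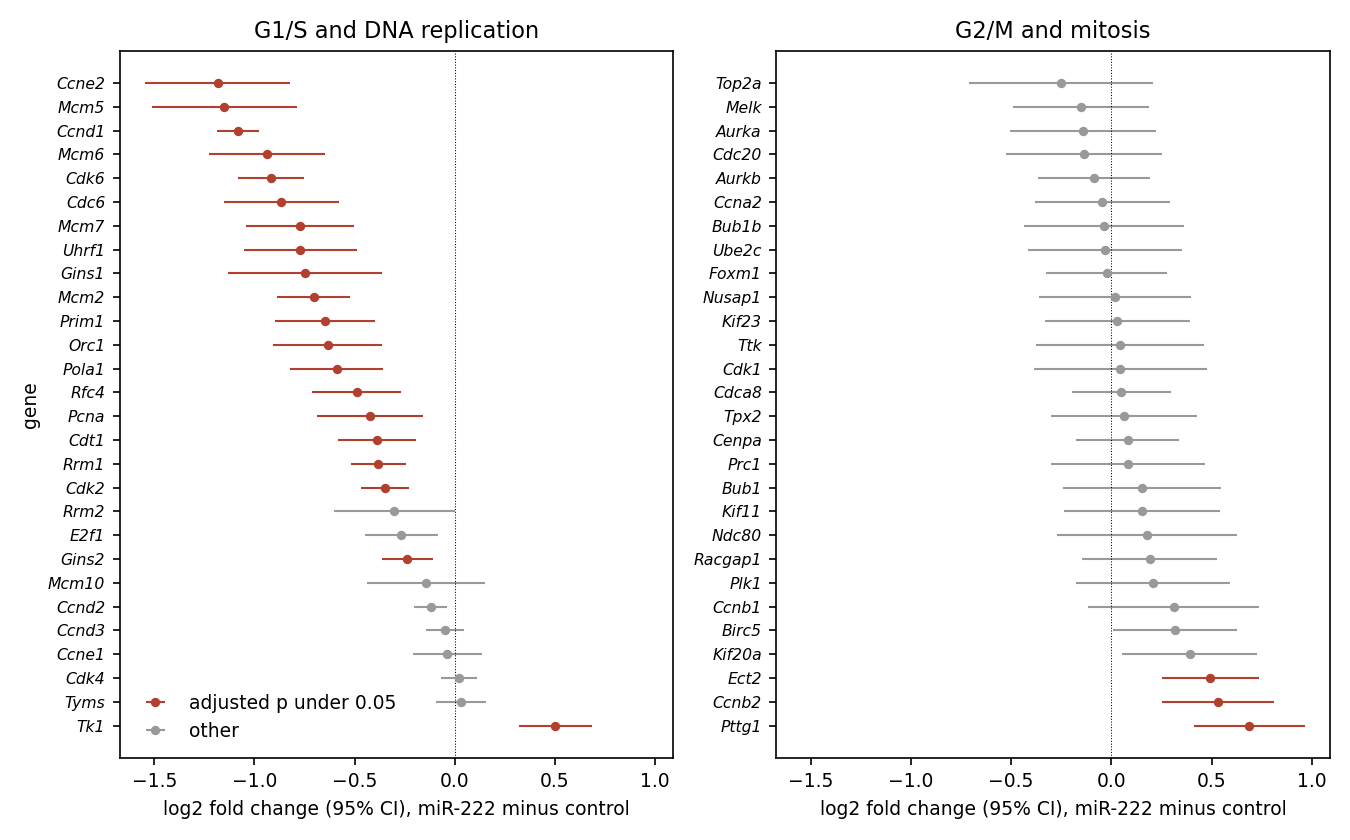
Log2 fold change (horizontal axis, miR-222 minus control, 4 arrays each) of each measured gene (vertical axis) of the G1/S and DNA replication list (left) and of the G2/M and mitosis list (right), with bars for the 95% confidence interval and red for an adjusted p under 0.05. On the left 19 of 28 genes lie below 0 in red and Tk1 above, and on the right Pttg1, Ect2 and Ccnb2 lie above 0 in red.

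Transcripts of the fetal and hypertrophic program of the heart were more often lower than higher. Of 15 measured members 7 fell, 1 rose and 7 did not pass, and 8 lower and 1 higher passed when adjusted over the list alone. The slow myosin gene Myh7 fell by 0.61 (SE 0.07, adjusted p = 6.58e-04), skeletal actin Acta1 by 0.27 (SE 0.04, adjusted p = 0.00368), the natriuretic peptide gene Nppa by 0.20 (SE 0.04, adjusted p = 0.00794) and Fhl1 by 0.46 (SE 0.09, adjusted p = 0.0101), whereas the atrial light chain gene Myl7 rose by 0.17, a call lost without control replicate 1, 2 or 3 or miR-222 replicate 1 (adjusted p up to 0.0729). The list lay below other genes (camera adjusted p = 0.0177), but adjusted p = 0.617 with an estimated correlation. Nppa and Acta1 were among the brightest probe sets, at 13.59 and 13.51 log2 units in control cells, where intensities near the top of the scale can compress a fold change.

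Of 23 measured genes of the sarcomere and of cardiomyocyte identity, 7 fell, 1 rose and 15 did not pass, and 10 lower and 2 higher passed when adjusted over the list alone. Besides Myh7, the Z-disc gene Ldb3 fell by 0.40 (SE 0.05, adjusted p = 8.67e-04), titin, Ttn, by 0.36 (SE 0.05, adjusted p = 0.00309) and the M-band gene Myom1 by 0.22 (SE 0.04, adjusted p = 0.0105). The cardiac factor gene Nkx2-5 was the member that rose, by 0.15, a call lost without any single array but miR-222 replicate 1 (adjusted p up to 0.0943). The list median was -0.09 (camera adjusted p = 0.00299), but adjusted p = 0.460 with an estimated correlation. miR-222 replicate 3 had the lowest list mean, -0.12 on the centred log2 scale, against -0.05 in each of the other 3 miR-222 arrays.

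Ion channel and calcium handling genes changed in both directions, with 4 of 21 measured members higher, 9 lower and 8 not past the threshold, and 5 higher and 11 lower when adjusted over the list alone. The members that rose were potassium channel genes, a reading made after their values were seen and not tested as a list. Kcnip2 went from 10.04 ± 0.11 to 11.71 ± 0.15 log2 units (mean ± SD, n = 4 each, limma adjusted p = 4.25e-05), and Kcnd2 and Kcnd3 rose by 1.12 (SE 0.24, adjusted p = 0.0149) and 0.43 (SE 0.09, adjusted p = 0.0125). Kcnh2, of the rapid delayed rectifier, rose by 0.36. The pacemaker channel gene Hcn4 fell by 0.62 (SE 0.05, adjusted p = 2.22e-04), the gap junction gene Gja1 by 0.40 (SE 0.06, adjusted p = 0.00222) and the calcium release gene Asph by 0.26 (SE 0.04, adjusted p = 0.00289). The list did not stand apart (camera adjusted p = 0.0888), and its median of -0.12 and the test differed in sign from its mean of 0.02. The count of 9 lower members was 5 without control replicate 1, 2 or 4.

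Genes of energy metabolism showed no common direction. Of 25 measured genes of fatty acid uptake and oxidation 6 rose and 3 fell (8 and 4 adjusted over the list alone), with a median of 0.05, and 0.01 without miR-222 replicate 3 (camera adjusted p = 0.410 with all arrays). The nuclear receptor gene Ppara rose by 0.50 (SE 0.09, adjusted p = 0.0053) and the acyl-CoA synthetase gene Acsl1 by 0.42 (SE 0.10, adjusted p = 0.0171), whereas Cpt1a, the liver form of the transferase that brings fatty acids into mitochondria, fell by 0.48 (SE 0.07, adjusted p = 0.0027), and so did Eci1, by 0.19, and Acadm, by 0.18. The list mean of miR-222 replicate 3 was 0.16 on the centred log2 scale, and those of the other 3 miR-222 arrays lay from -0.02 to 0.01. The 6 higher members were 2 or 3 when any single control array was left out, and Acadm was lost without control replicate 1, 2 or 3 (adjusted p up to 0.0606).

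Of 23 measured genes of oxidative phosphorylation, 3 fell and 20 did not pass, also when adjusted over the list alone (median 0.00, camera adjusted p = 0.411). They were Sdhd of complex II at -0.27 (SE 0.04, adjusted p = 0.00302) and Ndufb3 and Ndufa1 of complex I at -0.25 and -0.21. In glycolysis 2 of 20 measured genes rose and 3 fell, also when adjusted over the list alone (median 0.02, camera adjusted p = 0.817). The hexokinase gene Hk2 rose by 0.82 (SE 0.18, adjusted p = 0.0155) while Hk1 fell by 0.29 (SE 0.05, adjusted p = 0.00314) and the muscle enolase gene Eno3 by 0.45 (SE 0.08, adjusted p = 0.00713). Pfkp at -0.20 was lost without any array but control replicate 3 or miR-222 replicate 1 or 2 (adjusted p up to 0.0682), and the glucose transporter gene Slc2a1 at 0.28 without any but control replicate 4 or miR-222 replicate 4 (adjusted p up to 0.0818).

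In sterol synthesis 5 of 14 measured genes fell and 1 rose (6 and 2 adjusted over the list alone). They included Idi1 at -0.97 (SE 0.12, adjusted p = 0.001), the sterol sensor gene Insig1 at -0.40, Fdft1 at -0.34, Dhcr7 at -0.24 and Cyp51 at -0.25, and Msmo1 was higher at 0.20. Cyp51 was lost without control replicate 1 (adjusted p = 0.0512), and Msmo1 without any array but control replicate 4 or miR-222 replicate 3 (adjusted p up to 0.0648). That list did not stand apart (median -0.07, and -0.02 without miR-222 replicate 3, camera adjusted p = 0.237), and miR-222 replicate 3 had a list mean of -0.22 against -0.03 to -0.02 in the other 3 miR-222 arrays.

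Camera placed the markers of fibroblasts and matrix and those of smooth muscle and myofibroblasts below other genes, but adjusted p = 0.460 and adjusted p = 0.245 with an estimated correlation. The lists of the other cell types such a culture can hold did not stand apart. Of 23 measured fibroblast and matrix genes 15 fell and 8 did not pass, and 18 fell when adjusted over the list alone. Thbs1, encoding thrombospondin, fell by 0.90 (SE 0.06, adjusted p = 9.53e-05), fibronectin, Fn1, by 0.62 (SE 0.05, adjusted p = 1.98e-04), lumican, Lum, by 0.89 (SE 0.13, adjusted p = 0.00209) and the inhibitor gene Timp1 by 0.41 (SE 0.04, adjusted p = 5.02e-04). The collagen gene Col1a1 measured -0.04 (SE 0.06, adjusted p = 0.754). The list lay below other genes (median -0.24, camera adjusted p = 2.10e-07), but adjusted p = 0.460 with an estimated correlation. Without control replicate 3 the count of lower members was 9.

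Of 13 measured smooth muscle and myofibroblast genes 4 fell and 9 did not pass, and 6 fell when adjusted over the list alone. Tagln, an actin binding protein gene, fell by 0.91 (SE 0.07, adjusted p = 1.24e-04), Cspg4 by 0.72 (SE 0.06, adjusted p = 2.54e-04), the tropomyosin gene Tpm2 by 0.41 and the receptor gene Pdgfrb by 0.49. The list median was -0.11 (camera adjusted p = 0.0134), but adjusted p = 0.245 with an estimated correlation. Of 14 endothelial genes 2 fell, Kdr and, by 0.27, Eng, also when adjusted over the list alone (median -0.09, and -0.04 without control replicate 3, camera adjusted p = 0.216), and the mean level of that list was lower in each miR-222 array than in any control array. Of 17 macrophage and leukocyte genes 3 rose and 14 did not pass, also when adjusted over the list alone (median 0.05, camera adjusted p = 0.398). They were Cd74, a chaperone of antigen presentation, at 0.78 (SE 0.20, adjusted p = 0.0275), Cybb at 0.35 (SE 0.08, adjusted p = 0.0186) and C1qa at 0.26 (SE 0.08, adjusted p = 0.0471). Cd74 was lost without any single control array or miR-222 replicate 4 (adjusted p up to 0.0692), Cybb without control replicate 2 or 4 (adjusted p up to 0.0547) and C1qa without any array but control replicate 4 (adjusted p up to 0.118). None of 9 erythroid, Schwann cell and epicardial genes passed in limma, also when adjusted over the list alone (median 0.08, camera adjusted p = 0.646). At an unadjusted p under 0.05 there was 1, Wt1 at 0.14, a transcription factor gene of the epicardium.

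Most measured targets and ligands of TGF-beta and BMP signalling fell. Of 15 measured members 10 were lower and 5 did not pass, also when adjusted over the list alone. Id1 and Id3, inhibitors of basic helix-loop-helix factors that BMP induces, fell by 0.83 (SE 0.04, adjusted p = 4.41e-05) and 0.60 (SE 0.06, adjusted p = 5.20e-04), the ligand gene Tgfb3 by 0.54 (SE 0.06, adjusted p = 7.53e-04) and Ltbp2, which encodes a binding protein of the latent ligand family, by 0.33 (SE 0.05, adjusted p = 0.00235). The list lay below other genes (median -0.33, camera adjusted p = 1.41e-05), but adjusted p = 0.400 with an estimated correlation. miR-222 replicate 3 had a list mean of -0.33 on the centred log2 scale, against -0.16 to -0.13 in the other 3 miR-222 arrays. Fibroblast genes fell in the same arrays, and 1 gene, Ccn2, belonged to both lists.

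Immediate early genes, which respond first to growth signals, held 5 lower members of 19, 1 higher and 13 that did not pass (6 lower and 2 higher adjusted over the list alone). Dusp6, a phosphatase induced by ERK signalling, fell by 1.06 (SE 0.08, adjusted p = 1.25e-04), Egr1 by 0.56 (SE 0.08, adjusted p = 0.00191), Klf6 by 0.61 (SE 0.10, adjusted p = 0.00437) and Myc by 0.54 (SE 0.09, adjusted p = 0.00446). Klf4 at -0.17 was lost without control replicate 1, 2 or 3 or miR-222 replicate 1 (adjusted p up to 0.0562), and Fosl2 at 0.43 without any array but miR-222 replicate 1 or 4 (adjusted p up to 0.0762). The list did not stand apart from other genes (median -0.10, and -0.14 to -0.04 with single arrays left out, the last without miR-222 replicate 3, camera adjusted p = 0.216).

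Genes of microRNA biogenesis and silencing were lower in 4 of 8 measured members and did not pass in 4, and 6 were lower when adjusted over the list alone. Dicer1, which cuts microRNA precursors, fell by 0.29 (SE 0.05, adjusted p = 0.00481), the silencing factor gene Tnrc6a by 0.28 (SE 0.06, adjusted p = 0.0177), the nuclear processing gene Dgcr8 by 0.38 (SE 0.10, adjusted p = 0.0316) and the helicase gene Ddx6 by 0.18 (SE 0.04, adjusted p = 0.0142). The list lay below other genes (median -0.17, camera adjusted p = 0.0189), but adjusted p = 0.460 with an estimated correlation. Without control replicate 1, 2 members were lower. Tnrc6a was lost without control replicate 1 or 2 (adjusted p up to 0.0540) and Dgcr8 without control replicate 1, 3 or 4 or miR-222 replicate 1 or 2 (adjusted p up to 0.0849). With miR-222 replicates 2 and 3 both left out, a choice made after the data were seen, 1 member was lower and the list no longer passed (median -0.14, camera adjusted p = 0.0637).

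Targets of p53 rose more often than they fell, with 8 of 17 measured members higher, 2 lower and 7 not past the threshold, also when adjusted over the list alone. Cdkn1a at 0.47, the sestrin gene Sesn1 at 0.54 (SE 0.06, adjusted p = 8.88e-04) and Phlda3 at 0.31 (SE 0.04, adjusted p = 8.73e-04) were higher, whereas Gadd45a fell by 0.44 (SE 0.04, adjusted p = 3.77e-04) and Plk2 by 0.61, a call lost without any array but miR-222 replicate 1 or 4 (adjusted p up to 0.0766). The list stood above other genes (median 0.12, camera adjusted p = 0.0195), but adjusted p = 0.245 with an estimated correlation.

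Regulators of apoptosis went both ways, with 4 of 20 measured members higher and 4 lower, also when adjusted over the list alone (median 0.02, camera adjusted p = 0.934). Bak1, a pore-forming killer protein gene, had the smallest p of the named genes and fell by 1.21 (SE 0.04, adjusted p = 1.36e-05), the survival gene Bcl2 fell by 0.92 (SE 0.18, adjusted p = 0.00942), and Mcl1 and Bcl2l1 each fell by 0.23. The death receptor genes Fas and Tnfrsf10b rose by 0.54 (SE 0.07, adjusted p = 0.00111) and 0.32 (SE 0.04, adjusted p = 0.00177), and Bid rose by 0.52 and Diablo by 0.20. Bcl2l1 was lost without control replicate 1 or 2 (adjusted p up to 0.0541), and miR-222 replicate 3 had an apoptosis list mean of -0.05 on the centred log2 scale against -0.01 in the other 3 miR-222 arrays.

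Of 22 measured FoxO targets and members of the PI3K-Akt pathway 7 rose, 2 fell and 13 did not pass, and 11 rose and 3 fell when adjusted over the list alone. Foxo1 itself rose by 0.95 (SE 0.10, adjusted p = 5.78e-04), as did the muscle ubiquitin ligase genes Fbxo32 by 0.46 (SE 0.06, adjusted p = 0.00147) and Trim63 by 0.30 (SE 0.04, adjusted p = 0.00223). The insulin receptor substrate gene Irs1 fell by 0.43 (SE 0.04, adjusted p = 2.37e-04) and the receptor gene Igf1r by 0.21, a call lost without control replicate 1 or 4 or miR-222 replicate 4 (adjusted p up to 0.0704). The list stood above other genes (median 0.14, camera adjusted p = 0.0426), but adjusted p = 0.462 with an estimated correlation. That call was lost without control replicate 2 (adjusted p = 0.0632) or 4 (adjusted p = 0.0632) and without miR-222 replicate 2 (adjusted p = 0.0564) or 3 (adjusted p = 0.0568), and 4 members were higher without control replicate 1 or 4. miR-222 replicate 3 had a list mean of 0.14 on the centred log2 scale, against 0.03 in each of the other 3 miR-222 arrays.

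Stress lists had members on both sides, and camera placed none of the 3 apart from other genes. Of 20 genes of the unfolded protein response and amino acid stress 4 rose and 5 fell (5 and 5 adjusted over the list alone, median -0.03, camera adjusted p = 0.743). The stress factor genes Ddit3 at 0.81 (SE 0.13, adjusted p = 0.00312) and Trib3 at 0.78, Chac1 at 0.68 and the disulfide isomerase gene Pdia4 at 0.44 were higher, whereas Pdia6 at -0.46, Sdf2l1 at -0.45, Dnajc3 at -0.30, Manf at -0.18 and Xbp1 at -0.17 were lower. Chac1 was lost without any array but control replicate 4 or miR-222 replicate 1 (adjusted p up to 0.108), Manf without any but control replicate 4 or miR-222 replicate 2 (adjusted p up to 0.105) and Xbp1 without control replicate 1, 2 or 3 or miR-222 replicate 4 (adjusted p up to 0.0738).

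In the heat shock list 2 of 11 genes rose and 1 fell, also when adjusted over the list alone (median -0.04, camera adjusted p = 0.874). Hsp90aa1 rose by 0.22 (SE 0.04, adjusted p = 0.00517), whereas Hspb8 at 0.16 was lost without any array but miR-222 replicate 3 (adjusted p up to 0.0683) and Hspd1 at -0.13 without any single array (adjusted p up to 0.12). In the NRF2 list 1 of 15 genes rose, Txnrd1 at 0.29, and 2 fell, the quinone reductase gene Nqo1 at -0.54 (SE 0.07, adjusted p = 0.00181) and Gsta1 at -0.35, also when adjusted over the list alone (median -0.03, camera adjusted p = 0.694).

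Interferon-stimulated genes, which transfected RNA can induce, were higher in 4 of 24 measured members and did not pass in 20, also when adjusted over the list alone (median 0.05, camera adjusted p = 0.398). Both groups received transfected RNA, so the comparison cannot show whether transfection itself induced such genes. Psmb9 of the immunoproteasome rose by 0.44 (SE 0.06, adjusted p = 0.00208), Gbp2 by 0.37 (SE 0.05, adjusted p = 0.00222), Stat2 by 0.36 (SE 0.05, adjusted p = 0.00222) and Irf1 by 0.33, a call lost without control replicate 2 or 4 or miR-222 replicate 1 or 4 (adjusted p up to 0.0574). The miR-222 arrays differed on this list, with centred log2 means of -0.06, 0.15, -0.11 and 0.20 in replicates 1 to 4. Without replicate 2 the median was 0.00, and without replicate 4, 2 members were called lower.

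Among NF-kappaB targets and cytokines 1 of 22 members rose and 4 fell, also when adjusted over the list alone (median -0.03, camera adjusted p = 0.439). Nfkb2 rose by 0.31 (SE 0.06, adjusted p = 0.0062), and besides Ptgs2 the members Ccl2 at -0.43, Vcam1 at -0.33 and Ccl20 at -0.35 were lower. Ccl2 was lost without control replicate 1, 2 or 4 (adjusted p up to 0.0607), Vcam1 without control replicate 1, 2 or 3 or miR-222 replicate 4 (adjusted p up to 0.0636) and Ccl20 without control replicate 1 or 3 or miR-222 replicate 1 (adjusted p up to 0.0718). None of 19 ribosomal protein genes passed in limma, also when adjusted over the list alone (median 0.03, camera adjusted p = 0.339), and 2 did at an unadjusted p under 0.05, Rpl4 and Rpl13, each at 0.10. Another Rpl13 probe set, 10808601, went the other way at -0.17 (limma unadjusted p = 0.016), while the remaining Rpl13 probe sets lay at 0.10 to 0.11.

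Camera placed 10 of the 29 lists apart from other genes, 8 lower and 2 higher, and none with an estimated correlation, where 3 lists had an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 17 lists, of which 7 did not pass camera: the published targets, calcium handling, oxidative phosphorylation, endothelial, apoptosis and immediate early lists, all lower, and the ribosomal list, higher. An exact permutation test of the mean level of a list over the 8 arrays gave its smallest possible p (0.0286, 2-sided) in 19 of the 29 lists, 9 of which did not pass camera. Members named above to complete a count of 5 or fewer, and Mcm5 and Col1a1, were chosen after their values were seen.

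**Figure D3:**
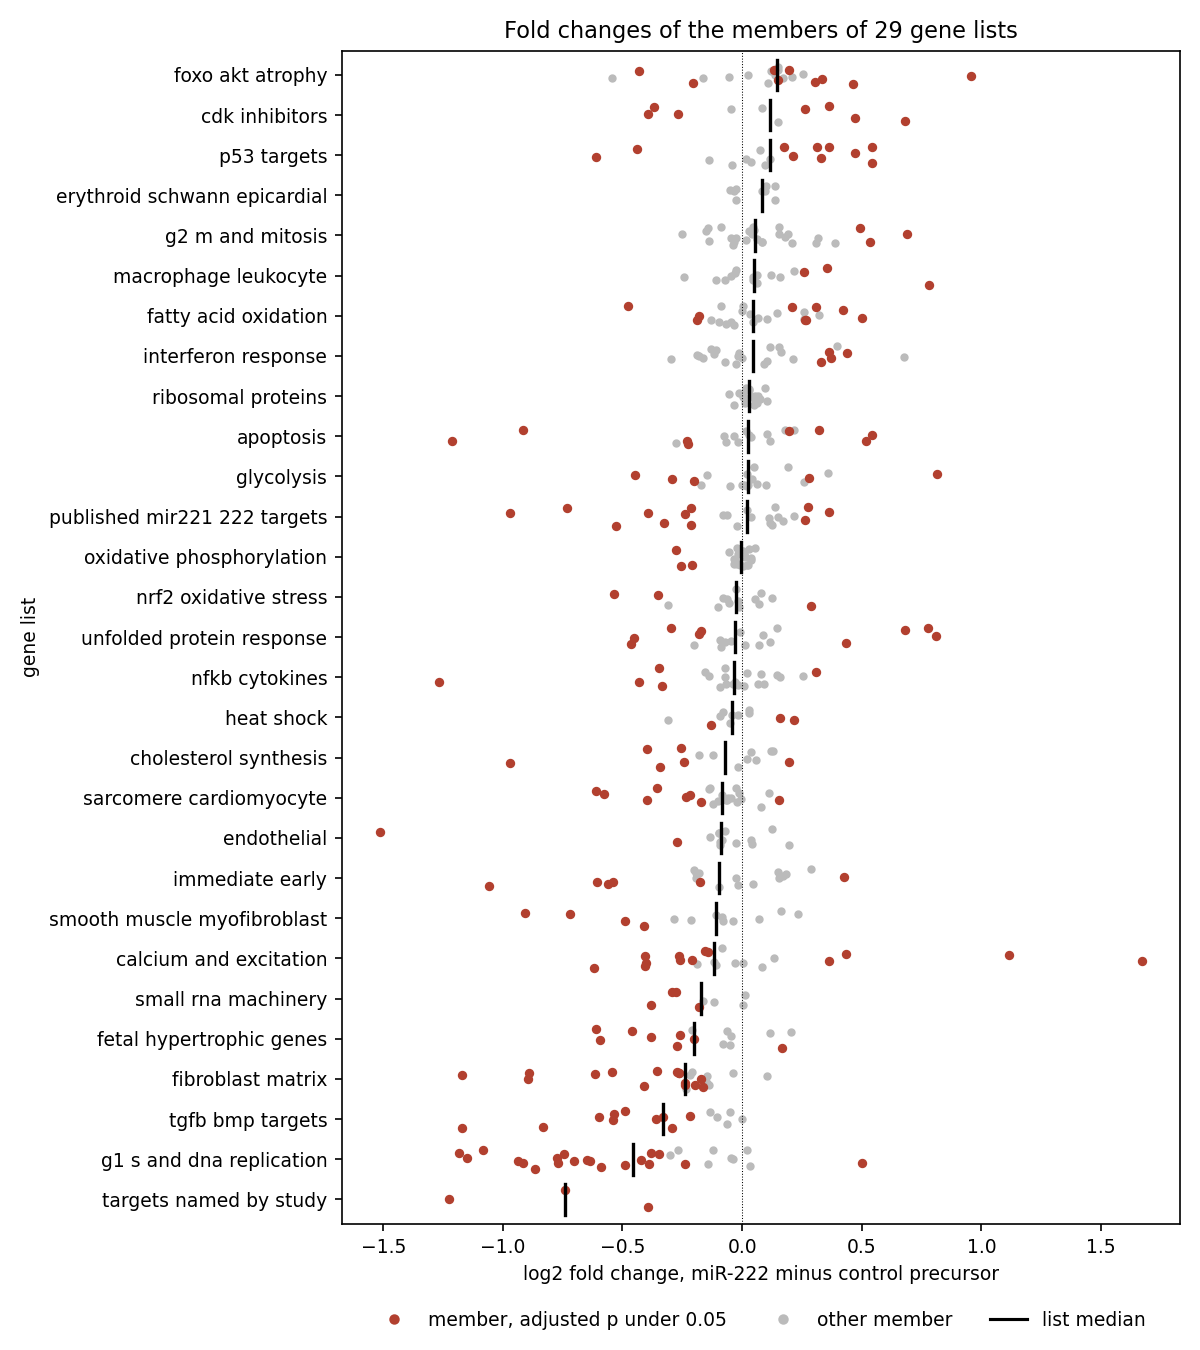
Log2 fold change (horizontal axis, miR-222 minus control) of each measured member of the 29 gene lists (vertical axis), with red points for an adjusted p under 0.05, grey points for other members and a black bar for the median of the list. The medians run from -0.74 for the targets named by the study and -0.46 for the G1/S list to 0.14 for the FoxO and Akt list.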

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

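The test of the mitosis genes of miR-222 replicate 3 was chosen only after the result was seen. In 330 groups of 4 arrays, each value was tested for a single array far from the other 3, by the gap to the nearest array as a share of the range of the group, against the 95% limit of Dixon's test. This was so in 31 groups, where chance gives about 1 in 20 groups, or 16.5, and 16 of the 31 were in miR-222 replicate 3.

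In miR-222 replicate 3 the log2 levels that stood apart were those of Cxcl11 (10.54, others 9.94 to 10.04), C3ar1 (7.228, others 8.39 to 8.56), Stx11 (8.745, others 9.44 to 9.56), Scn3b (8.813, others 10.25 to 10.37), Ccnb2 (10.51, others 10.81 to 10.84), Fhl1 (12.36, others 12.74 to 12.78), Ccl2 (11.45, others 11.80 to 11.87) and Klf6 (9.159, others 9.54 to 9.60). Its mean centred log2 level also stood apart for the lists of mitosis (-0.3655, others 0.18 to 0.21), sarcomere (-0.1189, others -0.05), fatty acid oxidation (0.1623, others -0.02 to 0.01), apoptosis (-0.05059, others -0.01), FoxO and Akt (0.1442, others 0.03), cholesterol synthesis (-0.2204, others -0.03 to -0.02) and TGF-beta and BMP (-0.3288, others -0.16 to -0.13). On the first principal component it lay at 0.5147, and the others lay at 0.27 to 0.30.

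In miR-222 replicate 2 these were Irs1 (8.561, others 8.60), Gsta1 (8.328, others 8.12 to 8.15), the heat shock list (0.054, others -0.04 to -0.03), the second principal component (0.7985, others -0.31 to -0.16) and the number of values at or near the floor (36, others 29 to 30). Among control arrays, replicate 1 stood apart for Plcxd3 (5.718, others 5.91 to 5.94), Wt1 (6.819, others 6.67 to 6.69) and Dicer1 (10.84, others 10.78 to 10.79), and replicate 2 for Ndufa1 (11.09, others 11.13) and the second principal component (0.3494, others -0.20 to -0.12). Control replicate 3 stood apart for Ccne2 (9.306, others 9.01 to 9.04), Myom1 (12.17, others 12.22), Insig1 (12.04, others 12.14 to 12.15) and Tnrc6a (10.51, others 10.60 to 10.61), and control replicate 4 for the fetal gene list (0.110, others 0.08 to 0.09).

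For miR-222 replicate 3, a candidate explanation is a stronger response of the same kind, for example from more precursor taken up. Over 8676 genes its deviation from replicates 2 and 4 rose with the effect measured in replicate 1 with a slope of 0.236 (r = 0.363 across genes, which are not independent). The mitosis genes went the other way, since their mean in replicate 3 lay 0.310 below the control mean (-0.3097, control SD 0.166). The other 3 miR-222 arrays lay above it (0.20 against -0.06 in control, where the lowest array lay at -0.26). This list was picked after its value was seen and the value comes from 1 array. Whether a stronger response is the whole explanation therefore stays open. Other differences, such as the density or the cell mix of this culture, were not tested.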

How the results depend on the processing

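Leaving out miR-222 replicates 2 and 3 together, leaving out replicate 3 with an estimated correlation (mitosis list adjusted p = 0.641), using only probe sets paired with 1 gene, and the pseudocount of 32 for the gene lists were chosen after seeing the data. The count of 5508 probe sets was 5606 after quantile normalization, with 5169 shared calls, and 4775 after a shift to equal medians, where 61.7% of the calls were lower against 52.7%. It was 6381 and 5758 in the upper 60% and 40% by level, 6476 with a trended robust prior, 6094 with array weights, 4222 with 1 probe set per gene, 4227 with their mean, 5793 with the pseudocount, 4457 with probe sets of 1 gene, 3972 without both arrays and 4066 (without control replicate 1) to 5379 (without miR-222 replicate 2) without single arrays. By construction fewer passed stricter thresholds: 813 (329 higher, 484 lower) at 1.5-fold and 2977 (1350 higher, 1627 lower) at an adjusted p under 0.01. Of the 10 lists camera placed apart, 0 passed with an estimated correlation, which by construction moves no median: targets named by the study -0.741 (adjusted p = 0.187), G1/S -0.455 (0.460), fetal genes -0.201 (0.617), sarcomere -0.0859 (0.460), fibroblasts -0.238 (0.460), smooth muscle -0.108 (0.245), p53 0.116 (0.245), FoxO and Akt 0.144 (0.462), TGF-beta and BMP -0.333 (0.400) and small RNA machinery -0.173 (0.460). Under the other alternatives 9 to 11 lists passed, the calcium list being added by the trended prior (adjusted p = 0.0301) and the mitosis list without miR-222 replicate 3 (adjusted p = 0.000931) or without both arrays (median 0.22, adjusted p = 0.00071). The FoxO and Akt list also missed the threshold in the upper 60% by level (0.144, adjusted p = 0.0769), with the mean of probe sets (0.144, 0.0512), without both arrays (0.103, 0.0989) and without control replicate 2 or 4 or miR-222 replicate 2 or 3 (adjusted p up to 0.0632), with medians of 0.122 to 0.162 without single arrays. The small RNA list missed it without both arrays (-0.143, adjusted p = 0.0637). The cause was not tested in these cases, nor for the estimated correlation. The correlations estimated for the targets named by the study, smooth muscle and p53 lists (-0.177, -0.0215 and -0.000729) lay below the preset 0.01. For these lists this argues against a higher correlation between members as the reason that the camera p-values rose. Among the 132 named genes, no direction reversed under any alternative run where the main fit or the alternative called the gene. Changes of sign in genes called in neither fit were not counted. Per alternative 0 to 12 calls were lost, most without control replicate 2. Without both arrays the 8 lost calls included Hk2 (0.55, adjusted p = 0.0594), Eng (-0.23, adjusted p = 0.0522) and Ddx6 (-0.16, adjusted p = 0.0726), which held without any single array. The seed-site alternatives were not run, since no genome was used here. No paired analysis was possible because the labels give no shared replicate numbers. Signal over background limits dim genes: of 10 equal groups of probe sets by level, 3.19% were called in the dimmest and 40.2% in the next to brightest.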

Other observations

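The tests of cycling cells in every phase alike and of a smaller share of fibroblasts were chosen only after the result was seen, and the ERK and YAP lists were written after the data were seen and tested on members not yet looked at. Among feedback and other output genes of ERK signalling, 4 of the 6 members not yet looked at were lower with miR-222. Besides Dusp6, the inhibitor genes Spry2 and Spry4 fell by 0.50 (SE 0.05, adjusted p = 6.04e-04) and 0.69 (SE 0.06, adjusted p = 1.90e-04), the phosphatase gene Dusp4 by 0.89 (SE 0.04, adjusted p = 3.61e-05) and the factor gene Etv5 by 0.47 (SE 0.07, adjusted p = 0.00202), with the 4 miR-222 arrays compared with 4 control arrays in limma. Etv4 at 0.02 and Epha2 at -0.12 did not pass.

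Genes that the growth regulator YAP induces went both ways. Of 13 members not yet looked at, 4 fell, among them Ccn1 by 0.92 (SE 0.13, adjusted p = 0.0018), the junction gene Ajuba by 0.77 (SE 0.05, adjusted p = 5.26e-05) and Amotl2 by 0.64 (SE 0.06, adjusted p = 3.55e-04), and 3 rose, Nt5e by 0.81 (SE 0.07, adjusted p = 1.81e-04), Asap1 by 0.35 and Fjx1 by 0.28. The fourth that fell was Axl, by 0.23. Within the fibroblast list, the 3 fibrillar collagen genes Col1a1, Col1a2 and Col3a1 measured -0.11 on average and the other members -0.37, a division made after their values were seen.

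The count of differing probe sets was compared over the 35 splits of the 8 arrays into 4 and 4. Only 1 split, the real one, gave as many as 5508 probe sets, and the highest of the others gave 0. A random division of these arrays is thus argued against for this count, at the smallest share that 35 splits allow. Every other split mixed both transfections, which widens the spread within its groups, and a difference of dish or batch was not excluded. For the count of gene lists, 2 of the 35 splits gave as many as 10 lists, the other being control replicates 1, 2 and 4 with miR-222 replicate 1, so chance cannot be excluded for the number of lists. In 10 equal groups of probe sets by level the largest median log2 fold change was 0.0452 in size. The values had already been normalized between arrays, which can itself hold these medians near 0. They therefore do not decide whether a shift of whole ranges of level added to the count. Shifting the arrays to equal medians changed it from 5508 to 4775 probe sets. Errors that move genes both ways within a range were not tested.

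The mean of the DNA replication list was lower in all 4 miR-222 arrays than in any control array, whereas that of the mitosis list was higher than in any control array in 3 of them (0.18 to 0.21, highest control 0.14). In miR-222 replicate 3 both were low, at -0.44 and -0.37, the latter below the lowest control array (-0.26), so a fall in every phase stays open for that array. For the group as a whole a fall of cycling cells in every phase alike is argued against, since the G1/S list mean minus the G2/M list mean changed by -0.598 (exact permutation p = 0.0286, the smallest possible), from 0.22 to 0.44 in control arrays to -0.42 to -0.08 in miR-222 arrays. Both lists were written beforehand, but their difference was tested after it had been seen, so this p-value is no independent support. By the rule written beforehand a changed share of dividing non-myocytes stays open. The fibroblast list median of -0.238 had the sign of the G1/S list but not of the mitosis list (median 0.06). A smaller share alone would lower both lists, which 3 of the miR-222 arrays did not show, but this reading was set after the data were seen. Slower entry into S phase and direct effects on these transcripts stay open.

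The fibroblast and matrix genes may be lower because the culture held fewer fibroblasts, which stays open, since the collagens differed from the other members by 0.263 but had been set apart after their values were seen. Whether the share of all non-myocytes fell also stays open. The medians of the 4 marker lists lay 0.289 apart, and a smaller share asked for all of them below -0.2, which smooth muscle (-0.11), endothelial (-0.09) and macrophage (0.05) genes did not meet, whereas against it the lowest had to lie below -0.3 and lay at -0.24. Abundant members stood at 11.47 (Col1a1) and 11.72 (Fn1) log2 units in control arrays. The list shares 1 gene, Ccn2, with the TGF-beta and BMP list, and how many of its genes cardiomyocytes express was not counted.

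As a hypothesis, lower output of ERK signalling may accompany the fall of Ccnd1 and Dusp6. The 6 members of the ERK list not yet looked at had a median of -0.483, and camera placed them below other genes (p = 1.82e-04, and p = 0.00859 with an estimated correlation). A second hypothesis, lower activity of YAP, was left undecided, since its 13 members had a median of -0.132 (camera adjusted p = 0.170) and went both ways.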
